A study of Rattus norvegicus with 6 samples.

How the data were processed

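RNA was measured in 6 libraries, 3 of vehicle-treated and 3 of ATRA-treated cardiomyocytes. Per the labels' protocols, minced ventricles of Wistar rat embryos were digested with trypsin and collagenase, fibroblasts were reduced by pre-plating, and the remaining cells were grown on laminin in medium with serum before the treatment. Poly(A) RNA was selected and libraries were made with a NEBNext Ultra II kit, per the labels' protocols. The submitters' processing notes name Trim Galore 0.6.4, STAR 2.7.3a, HTSeq 0.11.2 and DESeq2 1.32.0, and the rat build mRatBN7.2. The annotation release, the strand setting and the treatment of reads that map to several genes are not given in the sources used here. For this reason genes with close copies, such as Myh6 and Myh7 or Acta1, Acta2 and Actc1, have uncertain separate values, as have genes that overlap another gene.

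The deposited file is a results table of 23096 protein-coding genes. It holds, per the file headers, a normalised count signal per gene and library, in which the authors divided the reads of each library by a size factor. It also holds FPKM values by the authors, which equal the normalised count times a constant for each gene, within a relative spread of 4.5e-14, and were not otherwise used. The authors' own comparison is given as a log2 fold change with its standard error, a test score, a p-value and an adjusted p-value, per the file headers. Of these genes 3108 had no symbol, and 389 shared a symbol with another gene, where the symbol was kept for the one with the highest mean. No other per-sample columns were left out. Genomic positions were not used here, and the only annotation at hand was a table of gene names for the assembly GRCr8, used to match older symbols.

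The normalised counts of each library were whole multiples of its smallest value above 0, within a tolerance of 1e-08 for 100% of the values, which gave back the reads per gene and the depth of each library. For ATRA replicate 2 that step was 1.011, so close to 1 that it is hard to tell from rounding, although its values were whole multiples of it as well. The recovered totals were 25434878 to 32052035 reads, so that a gene with 3 reads in a library corresponds to 0.094 to 0.118 CPM, its reads scaled to a common library total. Counting intervals are exact 95% intervals of a ratio of reads and, like these floors, cover counting error only. No pair of libraries was a duplicate: chi-square per degree of freedom was 23.58 to 49.24 within vehicle and 2.59 to 3.43 within ATRA.

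The main test was limma 3.58.1 with a trended variance on log2(normalised count + 1), for genes with a normalised count of at least 10 in at least 3 libraries. An edgeR test had been planned for raw counts, with limma as the stated substitute should the table hold normalised values, as it did. Fold changes are therefore on the log2(value + 1) scale, which understates the change of low genes. Genes were called at a Benjamini-Hochberg adjusted p under 0.05 over all genes tested. All fold changes are ATRA against vehicle, given as log2 values with the standard error from limma and n = 3 libraries per group. Adjusted p-values for genes come from this limma test, and those for lists from limma's camera over the 33 lists with tested members, with a preset inter-gene correlation of 0.01 and, as an alternative, an estimated one. The fry test in limma and a two-sided Fisher's exact test of list members among called genes were run beside it. The test was checked on simulated counts for the same genes and libraries with 200 changed genes. With no changed gene, it called 0 genes and gave 4.72% of p-values under 0.05. The simulation drew genes independently and with the same dispersion in both groups. It therefore does not cover genes that move together or the larger spread of the vehicle libraries.

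The groups, the test, the alternatives, the gene lists and the rule for named genes were set before the data were examined. There were 34 lists with 775 entries, of which 24 did not match a symbol and were not analysed here, and 22 symbols stood in more than 1 list. The lists covered the retinoic acid response, retinoid metabolism and receptors, Hox genes, S phase and replication, G2/M and cytokinesis, G1 cyclins and CDK inhibitors, fetal and adult sarcomere genes, calcium handling and ion channels, fatty acid oxidation, oxidative phosphorylation, glycolysis, stress and natriuretic genes, cardiac transcription factors, atrial markers, markers of fibroblasts, endothelium, smooth muscle and pericytes, immune cells, epicardium, nerve and Schwann cells and erythroid cells, extracellular matrix remodelling, TGF-beta and BMP signalling, growth factor signalling, the interferon response, inflammatory cytokines, p53 and apoptosis, the unfolded protein and integrated stress response, the NRF2 and xenobiotic response, cholesterol synthesis, lipogenesis and LXR/PPARG targets, mitochondrially encoded transcripts and cytosolic ribosomal proteins. The text names the 12 largest rises and 12 largest falls among genes with a symbol, an adjusted p under 0.05, a mean of at least 2 CPM and no overlap between groups in CPM, up to 4 called members of each list by smallest p, and 20 genes named in advance whatever their result. Some genes that this rule takes are not reported here. Other genes are said to have been chosen after their values were seen. The difference between the means of a pair of lists per library was compared with a two-sided exact permutation test, which cannot go below 0.1 with 3 libraries per group.

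The alternatives were DESeq2 size factors or upper-quartile factors in edgeR 4.0.16 on the recovered reads, scaling by library size alone, no filter, a stricter filter of at least 5 CPM in 3 libraries, DESeq2 1.42.0, limma-voom, the replicate number as a block, each library left out in turn, a threshold of 0.01, a fold of at least 2, a test against a fold of 1.2 and pseudocounts of 0.5 and 5. The edgeR test with TMM factors on the recovered reads, which called 5146 genes, and limma with array weights were added after seeing the data. Principal components used log2 CPM with a prior count of 2. Analyses ran in R 4.3.3 and Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9.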

Results

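Poly(A) RNA was sequenced from cultured rat ventricular cardiomyocytes isolated at E18.5, a stage before birth. The cultures received 10 µM all-trans retinoic acid (ATRA), the active metabolite of vitamin A that activates the nuclear retinoic acid receptors, or the solvent DMSO as vehicle, for 48 h. There were 3 libraries in each group. The 6 libraries held 28190743, 32052035 and 25434878 gene-assigned reads for vehicle replicates 1 to 3 and 30368936, 29339996 and 27497967 for ATRA replicates 1 to 3, with 15969 to 16329 genes detected per library. Mitochondrially encoded transcripts took 6.86% to 7.31% of the reads. The labels do not say that the libraries of a group came from separate isolations, so the p-values measure only the spread between these samples, which may be technical.

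The series title sets the comparison in the context of retinoic acid signalling, exit of cardiomyocytes from the cell cycle and their maturation. ATRA changed a large part of the transcriptome. Of 13110 genes tested with limma, 2667 were higher and 2483 lower after ATRA, which is 39.3% of the genes tested, and 6364 had an unadjusted p under 0.05. The changes were mostly small, with a median absolute log2 fold change of 0.51 among called genes. At least 2-fold changes were seen for 445 higher and 836 lower genes, and at least 8-fold changes for 53 and 58. The groups did not overlap in normalised counts for 53.8% of tested genes, or in CPM for 56.2%, where chance gives 10%. With each library scaled by its total reads alone, 1765 genes were higher and 3769 lower, because the median of all genes then lay at -0.104 and not at 0.004. Upper-quartile scaling gave 2178 higher and 3042 lower. Leaving out ATRA replicate 1, 2 or 3 lowered the number of called genes to 3402, 3416 or 3360.

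The enzymes that degrade or store retinoids showed the largest rises of all genes covered by the naming rule. Cyp26a1 (ENSRNOG00000016750), a cytochrome P450 that hydroxylates and inactivates retinoic acid, went from 44 ± 10.8 to 42441 ± 432 normalised counts (SD, n = 3), a 961-fold rise (log2 fold change 9.91 ± 0.14, SE, adjusted p = 3e-08). Cyp26b1 (ENSRNOG00000015076), a related enzyme, rose 598-fold from 97.1 ± 25.6 to 57223 ± 2663 normalised counts (9.22 ± 0.18, adjusted p = 5.1e-08). Cyp26c1 and Lrat, which esterifies retinol for storage, were nearly silent in vehicle. Cyp26c1 had 9 reads over the vehicle libraries and 6171 over the ATRA libraries, a ratio of 674 with a 95% counting interval of 355 to 1470, and Lrat had 10 and 4471 reads, a ratio of 439 (239 to 917). Dhrs3, which reduces retinaldehyde back to retinol, rose 31.6-fold (4.98 ± 0.09), and the receptor gene Rarb rose 10.1-fold from 203 ± 58 to 1988 ± 27.4 normalised counts (3.33 ± 0.2, adjusted p = 1.8e-05).

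**Figure D1:**
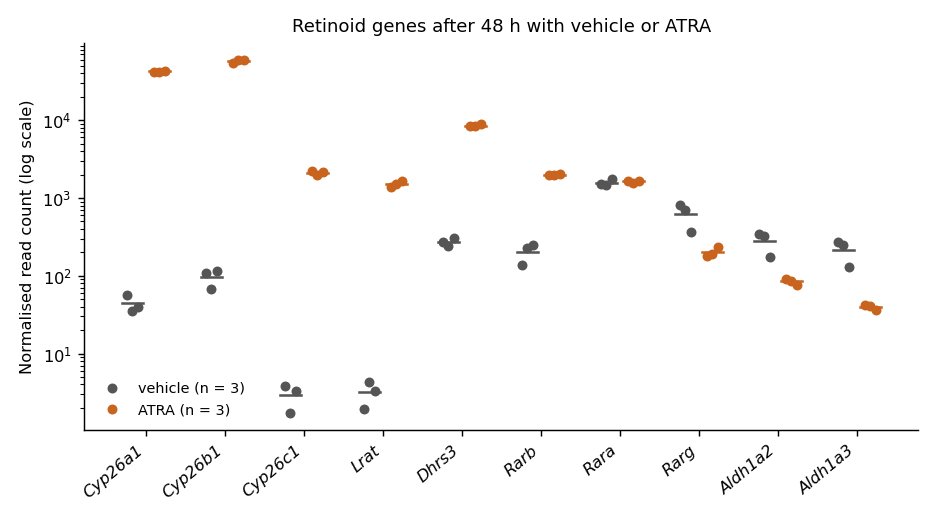
Normalised read counts of 10 retinoid genes in each of the 3 vehicle and 3 ATRA libraries, on a log axis, with a horizontal line at each group mean. Cyp26a1 and Cyp26b1 averaged 42441 and 57223 normalised counts after ATRA, against 44 and 97.1 in vehicle, while Rara was 1569 in vehicle and 1633 after ATRA; Rarg was added to the plot after its values were seen.

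Among the 13 tested members of the retinoic acid response list, 9 were higher, 3 lower and 1 not called, with a median log2 fold change of 3. Adjusted over the list alone, 9 were higher and 4 lower. The list was called as a whole by camera (adjusted p = 0.00011), and had adjusted p = 0.29 with an estimated correlation. The 3 lower members, chosen after their values were seen, were Rai14 (-0.85 ± 0.07), Crabp2 (-0.92 ± 0.31), which encodes a cytosolic retinoic acid binding protein, and Rarres2 (-0.91 ± 0.31). Leaving out vehicle replicate 1 or 2 or ATRA replicate 1, 2 or 3 left 1 lower member, as did the stricter filter, no filter or DESeq2. With no filter on low values the median of the list was 0.44, and with DESeq2 0.43. Aldh1a3 was 5.14-fold lower (-2.36 ± 0.27, adjusted p = 0.00048) and Aldh1a2 3.18-fold lower (-1.67 ± 0.25, adjusted p = 0.0017), and both encode retinaldehyde dehydrogenases, which make retinoic acid. The nuclear receptor gene Rxrg rose 5.52-fold (2.47 ± 0.25, adjusted p = 0.00029), whereas Rara did not pass the test (0.06 ± 0.08, adjusted p = 0.56, and -0.05 with library size alone). In the list of retinoid metabolism and receptors, 3 of 12 tested members were higher and 5 lower, the same counts as adjusted over the list alone, and camera made no call (median -0.15, adjusted p = 0.41), with a median of 0.04 and 3 lower members under the stricter filter, and a median of -0.08 with no filter, -0.26 with library size alone and -0.33 with DESeq2. Bco1 (-1.93 ± 0.29) was also lower. The remaining called members, chosen after their values were seen, were Rxrb (0.32 ± 0.05) and Rdh11 (0.36 ± 0.07) among the higher and Rxra (-0.38 ± 0.06) and Rarg (-1.56 ± 0.27) among the lower. Hox genes, the classic positional targets of retinoic acid, were barely detected. Of 30 Hox symbols, 19 had any read, 11 had none, none reached the expression filter, and the highest normalised count was 13.9.

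Beyond the retinoid genes, Vil1, which encodes the actin-bundling protein villin, rose 54.4-fold (5.77 ± 0.11), and Irag1, a substrate of cGMP-dependent protein kinase, 46.2-fold (5.53 ± 0.1). Steap4, a metalloreductase, rose 34.6-fold (5.11 ± 0.21), and Wif1, a secreted Wnt inhibitor, 32-fold (5 ± 0.08). Lmln2, Gpc5 and Cnih3 also ranked among the 12 largest rises and had 10, 23 and 10 reads over the vehicle libraries, with ratios of 81.9 (95% counting interval 44.3 to 172), 37.5 (24.8 to 59.5) and 40.4 (21.7 to 84.8). The largest fall was that of Corin, the protease that activates pro-atrial natriuretic peptide, which went from 278 ± 57.7 to 8.32 ± 5.55 normalised counts (SD, n = 3), 33.9-fold lower (-5.08 ± 0.44, adjusted p = 0.00013). The transcription factor genes Fosb and Atf3 were 28.7-fold (-4.84 ± 0.23) and 25.1-fold lower (-4.65 ± 0.18). Ntrk2, which encodes the receptor TrkB, was 19.9-fold lower (-4.31 ± 0.19), and Acan, which encodes the proteoglycan aggrecan, 18.1-fold lower (-4.17 ± 0.44). The other large falls were those of Anxa8 (-4.67), Nptx1 (-4.15), Grem1 (-4.08, and -4.89 without vehicle replicate 3), Ereg (-4.05), Pkp1 (-3.97), Aldh3a1 (-3.85) and Ca3 (-3.66). Vehicle replicate 3 had the lowest vehicle value for each of these, for Acan and, narrowly, for Fosb, but the highest for Corin and Ntrk2. In that library 16 of 17 fibroblast markers were also lower than in the mean of the other vehicle libraries. Each of the 24 genes with the largest rises and falls was on the same side of the threshold in every setting in which it was tested.

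DNA replication genes were mostly lower, by a modest amount. Of 35 tested members of the S phase and replication list, 28 were lower, 0 higher and 7 not called, with a median log2 fold change of -0.45, or 1.36-fold lower. The 4 with the smallest p were the replicative helicase subunit gene Mcm6 (-0.76 ± 0.06, adjusted p = 6e-05), Rrm2, a subunit of ribonucleotide reductase (-0.68 ± 0.07, adjusted p = 0.00026), Uhrf1, which guides maintenance DNA methylation (-0.79 ± 0.08, adjusted p = 0.00034), and Gins2, another helicase component (-1.06 ± 0.12, adjusted p = 0.00053). Adjusted over the list alone, 32 were lower. Camera called the list (adjusted p = 1.4e-09), which had adjusted p = 0.29 with an estimated correlation.

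The mitotic genes were not called as a list. In the G2/M and cytokinesis list 35 of 39 tested members were not called, 3 were lower and 1 was higher, and adjusted over the list alone 2 were lower. The median was 0.03 and the mean 0.02, while the camera test pointed down (adjusted p = 0.84). The proliferation marker Mki67 had 2933 ± 207 normalised counts in vehicle and 2877 ± 17.1 after ATRA (SD, n = 3; -0.03 ± 0.06, adjusted p = 0.76, and 0.03 without vehicle replicate 2). Ccnb1, the mitotic cyclin B1, had 0.21 ± 0.12 (adjusted p = 0.21), and its kinase Cdk1 -0.2 ± 0.09 (adjusted p = 0.12), which was called without vehicle replicate 3 (-0.31, adjusted p = 0.0033), with library size alone (0.027) and with array weights (0.015). The called members were Melk (-0.54 ± 0.1), Esco2 (-0.54 ± 0.12), Cdc25c (-0.34 ± 0.11) and Kif20a (0.43 ± 0.14). Cdc25c lost its call when vehicle replicate 1 or 2 or any ATRA library was left out (adjusted p = 0.094, 0.071, 0.08, 0.1 and 0.13), with no filter (0.055) and with DESeq2 (0.068). Kif20a lost it without vehicle replicate 1 or any ATRA library (0.058, 0.1, 0.1 and 0.14) and with library size alone (0.1). In edgeR it lost the call with DESeq2 size factors (0.051), upper-quartile factors (0.075) or TMM factors (0.054). The Cdc25c and Kif20a calls were also lost with the replicate number as a block. Without vehicle replicate 3 Kif20a kept its call, with a log2 fold change of 0.26. All 39 members were lower in vehicle replicate 3 than in the mean of vehicle replicates 1 and 2, by a median of -0.4 on the log2 scale. Without vehicle replicate 3, 3 members were higher and 12 lower (median -0.1), and without vehicle replicate 2, 8 were higher (median 0.13). The count of higher members was 0 without vehicle replicate 1 or any ATRA library and in edgeR with any of the 3 sets of factors, and 3 with DESeq2. With library size alone 0 were higher and 8 lower (median -0.08), with array weights 3 and 10 (median -0.07), and with upper-quartile factors 0 and 5 (median -0.05). The mean S phase level minus the mean G2/M level was taken per library, relative to the vehicle mean of this difference. It lay between -0.51 and -0.46 in the ATRA libraries and between -0.24 and 0.24 in the vehicle libraries (difference -0.48, two-sided exact permutation p = 0.1, the smallest this design allows).

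**Figure D2:**
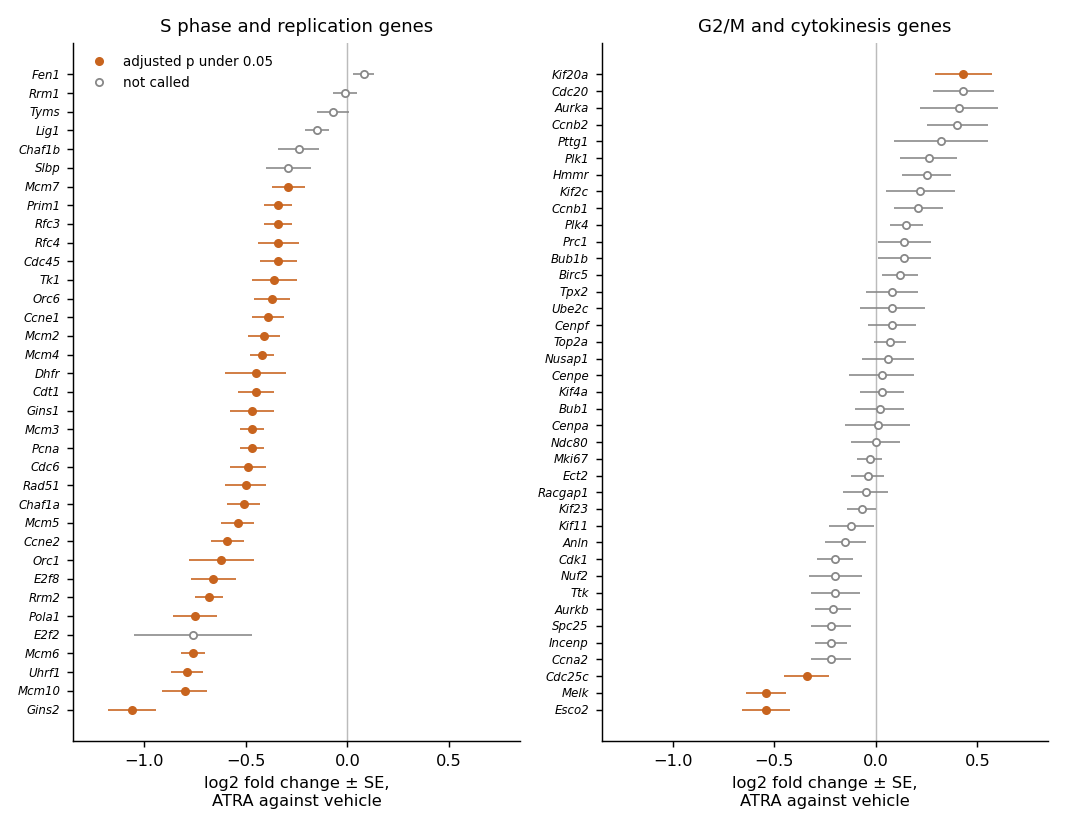
Log2 fold change after ATRA, with its standard error from limma, of each tested member of the S phase and G2/M lists (n = 3 libraries per group). The S phase members have a median of -0.45 and the G2/M members a median of 0.03.

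Genes that control entry into the cell cycle went both ways. Among 20 tested G1 cyclins and CDK inhibitors, 5 were higher, 7 lower and 8 not called, the same counts of calls as adjusted over the list alone, with a median of -0.07 and no call by camera (adjusted p = 0.34). The median was -0.14 or -0.12 without vehicle replicate 1 or 2, -0.15 without ATRA replicate 1 or with upper-quartile factors, -0.18 with library size alone, -0.12 with array weights and -0.11 with TMM factors. Btg2, an antiproliferative gene, was 3.18-fold lower (-1.67 ± 0.11, adjusted p = 3.8e-05), and the CDK inhibitor gene Cdkn1a was lower as well (-0.58 ± 0.1, adjusted p = 0.0027). The homeobox genes Meis2 (0.64 ± 0.07, adjusted p = 0.00045) and Meis1 (0.65 ± 0.09, adjusted p = 0.00092) and the CDK inhibitor gene Cdkn2d (0.74 ± 0.1, adjusted p = 0.0009) were higher, as were Cdk2 (0.4 ± 0.07) and Cdkn1b (0.19 ± 0.06), these last chosen after their values were seen. Ccnd1, or cyclin D1, was not called (0.26 ± 0.12, adjusted p = 0.12), but passed the test without vehicle replicate 1 (0.41, adjusted p = 0.0016) and with array weights (adjusted p = 0.02).

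Contractile protein genes moved in both directions within the fetal and the adult groups. Myh6, the fast alpha myosin heavy chain, rose 2.8-fold from 107189 ± 22352 to 295902 ± 17204 normalised counts (SD, n = 3; 1.49 ± 0.16, adjusted p = 0.00037), while Myh7, the slow beta chain that is abundant in the fetal ventricle, was lower (-0.63 ± 0.16, adjusted p = 0.015). The Myh7 call was lost without ATRA replicate 1, 2 or 3 (adjusted p = 0.076, 0.054 and 0.069). The slow skeletal troponin I gene Tnni1, the fetal isoform, was 2.15-fold higher (1.11 ± 0.11, adjusted p = 2e-04), and the adult isoform Tnni3 was not called (0.34 ± 0.13, adjusted p = 0.067), though it was without vehicle replicate 3 (0.5, adjusted p = 2e-04), with DESeq2 (0.04) and with array weights (0.002). Myom2, an M-band protein gene, was 3.79-fold lower (-1.92 ± 0.12), the small heat shock protein gene Cryab 2.02-fold lower (-1.01 ± 0.07) and Lmod2, an actin filament nucleator, 1.92-fold lower (-0.94 ± 0.08). Acta2 and Tagln, which encode smooth muscle actin and transgelin and mark both immature myocytes and smooth muscle, rose 2.36-fold (1.24 ± 0.1) and 1.87-fold (0.91 ± 0.08). Reads shared between the close pairs Myh6 and Myh7 and among the actin genes Acta1, Acta2 and Actc1 leave their separate values uncertain.

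Of 12 tested fetal or neonatal sarcomere isoforms, 7 were higher and 4 lower, and 8 and 4 adjusted over the list alone, with a median of 0.46 and no call by camera (adjusted p = 0.22). The lower members were Myh3 (-3.15 ± 0.35), the embryonic skeletal myosin, Myl7 (-0.76 ± 0.13), Myh7 and Actn1 (-0.23 ± 0.07). Myl7 and Actn1 were chosen after their values were seen. Leaving out ATRA replicate 1, 2 or 3 left 3 higher and 2 lower each time. In the adult sarcomere and structure list, 8 of 26 tested members were higher, 6 lower and 12 not called, and 13 and 6 adjusted over the list alone (median 0.24, or 0.13 with library size alone, camera adjusted p = 0.31). The higher count was 15 without vehicle replicate 3, 4, 4 and 5 without ATRA replicate 1, 2 and 3, 13 with DESeq2, 12 with array weights and 5 with library size alone. The adult sarcomere members had a median of 0.25 in vehicle replicate 3 relative to the other vehicle libraries.

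Genes of excitation and calcium handling also split. Kcne1, the auxiliary subunit of the slow delayed rectifier potassium channel, rose 17.7-fold from 98.5 ± 8.85 to 1753 ± 25 normalised counts (SD, n = 3; 4.14 ± 0.09, adjusted p = 8.3e-08). Adrb1, the main cardiac beta-adrenergic receptor, rose 5.13-fold (2.36 ± 0.16, adjusted p = 3.8e-05). Sln, the sarcolipin gene of atrial muscle, was 4.45-fold lower (-2.15 ± 0.16, adjusted p = 6.6e-05), and Gja1, the main ventricular connexin, 1.84-fold lower (-0.88 ± 0.08, adjusted p = 0.00022). Over the list, 13 of 33 tested members were higher, 8 lower and 12 not called, and 15 and 8 adjusted over the list alone, with a median of 0.27. Camera did not call it (adjusted p = 0.16). In vehicle replicate 3 its members had a median of 0.23 relative to the other vehicle libraries, and without that library 20 were higher, the median was 0.41 and camera gave adjusted p = 0.017. The median was 0.15 without vehicle replicate 1 and 0.16 with library size alone, 20 were higher with array weights, 5 were lower under the stricter filter, and with DESeq2 in place of limma camera gave adjusted p = 0.031.

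Fatty acid oxidation genes were mostly higher. Of 28 tested members, 22 were higher, 0 lower and 6 not called, counts that were unchanged when adjusted over the list alone, with a median log2 fold change of 0.61, or 1.53-fold. Ucp2, a mitochondrial carrier, rose 1.84-fold from 7175 ± 191 to 13177 ± 293 normalised counts (SD, n = 3; 0.88 ± 0.05, adjusted p = 1.4e-05). Cpt1a, which admits long-chain fatty acids to the mitochondrion, rose 1.72-fold (0.78 ± 0.07, adjusted p = 0.00011), Etfdh 1.81-fold (0.85 ± 0.08, adjusted p = 0.00015) and Hadh, an enzyme of beta-oxidation, 1.9-fold (0.93 ± 0.09, adjusted p = 0.00019). The regulator Ppargc1a (0.28 ± 0.14, adjusted p = 0.16) and the muscle isoform Cpt1b (0.2 ± 0.2, adjusted p = 0.46) were not called. Cpt1b was called with array weights (adjusted p = 0.049) and without vehicle replicate 3 (0.46, adjusted p = 0.00019), the library in which the list members had a median of 0.24 relative to the other vehicle libraries. In the ATRA libraries the list averaged 0.61 relative to the vehicle mean while the fibroblast markers averaged -0.81. In vehicle replicate 3 these means were 0.18 and -0.64. Camera called the list (adjusted p = 4.3e-09), with adjusted p = 0.69 with an estimated correlation.

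Nuclear genes of the respiratory chain and the citric acid cycle were mostly higher as well. In the oxidative phosphorylation list 30 of 37 tested members were higher, 1 lower and 6 not called, and 31 and 1 adjusted over the list alone. The median was 0.34, or 1.26-fold, and camera called the list (adjusted p = 1.9e-08), with adjusted p = 0.69 with an estimated correlation. The cytochrome c oxidase subunit genes Cox4i1 (0.39 ± 0.05, adjusted p = 0.00096) and Cox5b (0.4 ± 0.05, adjusted p = 0.00098) and the complex III gene Uqcrc1 (0.45 ± 0.06, adjusted p = 0.0011) were examples, and the lower member, chosen after its values were seen, was Cox6a2 (-0.26 ± 0.06). Vehicle replicate 3 had a median of 0.18 for these genes relative to the other vehicle libraries. Transcripts encoded in the mitochondrial genome showed fewer calls. Of 13 members 2 were higher, also when adjusted over the list alone, namely Mt-nd4l (0.24 ± 0.05) and Mt-nd5 (0.31 ± 0.08), and the median was 0.05, or 0.01 without vehicle replicate 3, 0 with upper-quartile factors and -0.06 with library size alone, under which neither was called and 1 member was lower (camera adjusted p = 0.34). Mt-nd5 lost its call without ATRA replicate 1, 2 or 3 (adjusted p = 0.074, 0.087 and 0.091) and with the replicate number as a block, each of which left 1 higher member. There were 4 higher without vehicle replicate 1 or 3, with limma-voom, array weights or edgeR with DESeq2 size factors, and 5 with DESeq2. The mean of the oxidative phosphorylation genes minus that of the mitochondrially encoded ones was taken per library, relative to the vehicle mean of this difference. It was 0.23 to 0.25 in the ATRA libraries and -0.17 to 0.17 in vehicle (difference 0.24, two-sided exact permutation p = 0.1, the smallest possible).

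Glycolysis and lactate transport genes were mostly higher too. Slc16a3, which encodes the lactate exporter MCT4, rose 8.22-fold from 2474 ± 656 to 19882 ± 157 normalised counts (SD, n = 3; 3.04 ± 0.16, adjusted p = 1.2e-05), the muscle phosphoglycerate mutase gene Pgam2 rose 4.27-fold (2.09 ± 0.14, adjusted p = 3.2e-05), and Pfkp and Pfkfb3, which act at the phosphofructokinase step, rose 1.69-fold (0.76 ± 0.06) and 1.83-fold (0.87 ± 0.07). Of 25 tested members 16 were higher, 1 lower and 8 not called, and 18 and 1 adjusted over the list alone. The lower member was Hk2 (-0.46 ± 0.06), chosen after its values were seen, and 2 were lower without vehicle replicate 1, with library size alone or with upper-quartile factors. The median was 0.33, and camera called the list (adjusted p = 1.2e-05), with adjusted p = 0.61 with an estimated correlation.

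Lipid synthesis and cholesterol efflux genes were also mostly higher. Abcg1 and Abca1, cholesterol exporters and targets of the liver X receptors, rose 4.66-fold (2.22 ± 0.1, adjusted p = 4.5e-06) and 6.21-fold (2.63 ± 0.18, adjusted p = 4.1e-05). Acacb, the acetyl-CoA carboxylase of the mitochondrial surface, rose 4.23-fold from 1307 ± 254 to 5456 ± 360 normalised counts (SD, n = 3; 2.08 ± 0.14, adjusted p = 3.2e-05), and Lpcat3 2.49-fold, from 2295 ± 298 to 5688 ± 59.4 normalised counts (SD, n = 3; adjusted p = 4e-05). In the list of lipogenesis and LXR/PPARG targets 13 of 18 tested members were higher, 1 lower and 4 not called, the same as adjusted over the list alone (median 1.15). Camera called it (adjusted p = 6.3e-07), with adjusted p = 0.53 with an estimated correlation. The lower member, Mylip (-0.75 ± 0.23), was chosen after its values were seen, and the lower count was 0 without vehicle replicate 1 or 2 or any ATRA library or under the stricter filter. The members had a median of -0.35 in vehicle replicate 3 relative to the other vehicle libraries.

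For cholesterol synthesis the result depended on single libraries. There were 6 higher, 0 lower and 12 uncalled genes among 18 tested, and 5 higher adjusted over the list alone, with Stard4, a sterol carrier (1.16 ± 0.17, adjusted p = 0.0014), as an example. The median was 0.37 and camera called the list (adjusted p = 0.016), with adjusted p = 0.69 with an estimated correlation. All 18 members were lower in vehicle replicate 3 than in the mean of the other vehicle libraries, by a median of -0.65. Without that library 3 were lower, the median was 0.19 and camera gave adjusted p = 0.3, and without vehicle replicate 2, 12 were higher with a median of 0.59. Leaving out ATRA replicate 1, 2 or 3 left 3, 2 or 3 higher. The camera call was also lost with DESeq2 (adjusted p = 0.064), limma-voom (adjusted p = 0.15) and array weights (median 0.2, adjusted p = 0.12, 1 lower).

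Stress and natriuretic genes were mostly lower. Atf3 went from 4139 ± 995 to 163 ± 27.7 normalised counts (SD, n = 3; -4.65 ± 0.18, adjusted p = 2.4e-06). Hbegf, an epidermal growth factor family ligand, was 4.11-fold lower (-2.04 ± 0.09, adjusted p = 5.2e-06), Fos 11.2-fold lower (-3.48 ± 0.2, adjusted p = 1.5e-05) and the matricellular gene Ccn1 2.52-fold lower (-1.33 ± 0.09, adjusted p = 4.5e-05). The natriuretic peptide gene Nppb was lower (-0.49 ± 0.09, adjusted p = 0.0052). Nppa was lower by a small margin (-0.42 ± 0.14, adjusted p = 0.048), a call lost without vehicle replicate 2 (-0.3, adjusted p = 0.13) and without ATRA replicate 1, 2 or 3 (adjusted p = 0.15, 0.18 and 0.18), with no filter (0.066) and with a pseudocount of 5 (0.054). It was also lost with the replicate number as a block. Of 19 tested stress and natriuretic genes 15 were lower, 2 higher and 2 not called, the same as adjusted over the list alone, with a median of -0.88. Camera called the list (adjusted p = 1.6e-06), with adjusted p = 0.53 with an estimated correlation. The higher members, chosen after their values were seen, were Xirp1 (0.41 ± 0.1) and Acta1 (0.46 ± 0.12), and their number was 1, 0 and 0 without ATRA replicate 1, 2 and 3.

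Among cardiac transcription factors, Hey2, which is enriched in ventricular over atrial muscle, rose 3.16-fold (1.66 ± 0.1, adjusted p = 2.2e-05) and Myocd, the coactivator myocardin, 2.11-fold (1.08 ± 0.12, adjusted p = 0.00041), while Irx3 was 2.68-fold lower (-1.42 ± 0.14, adjusted p = 2e-04) and Esrrg, an oestrogen-related receptor, 1.69-fold lower (-0.75 ± 0.08, adjusted p = 0.00026). Of 29 tested, 9 were higher, 5 lower and 15 not called, and 10 and 5 adjusted over the list alone. The other lower members, Mef2a (-0.41 ± 0.05), Irx5 (-0.92 ± 0.15) and Nr2f2 (-1.05 ± 0.2), were chosen after their values were seen. Camera made no call (median 0.07, adjusted p = 0.48), the median was -0.04 with library size alone, 0.02 with upper-quartile factors, 0.11 with no filter, 0.17 under the stricter filter, 0.14 with array weights and -0.01, 0.12 and 0.22 without vehicle replicate 1, 2 and 3, and 15 were higher without vehicle replicate 3, where the members had a median of 0.22 relative to the other vehicle libraries. The atrial markers that were called were lower. Of 13 tested, 7 were lower, 0 higher and 6 not called, and 8 and 2 adjusted over the list alone (median -0.42, camera adjusted p = 0.014, and adjusted p = 0.61 with an estimated correlation). Sln (-2.15 ± 0.16), Stard10 (-0.83 ± 0.1), the atrial connexin gene Gja5 (-1.63 ± 0.21) and Bmp10 (-0.72 ± 0.12) had the smallest p. The higher count was 1 without vehicle replicate 1 or 3 or ATRA replicate 1, with DESeq2 and under the stricter filter.

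**Figure D3:**
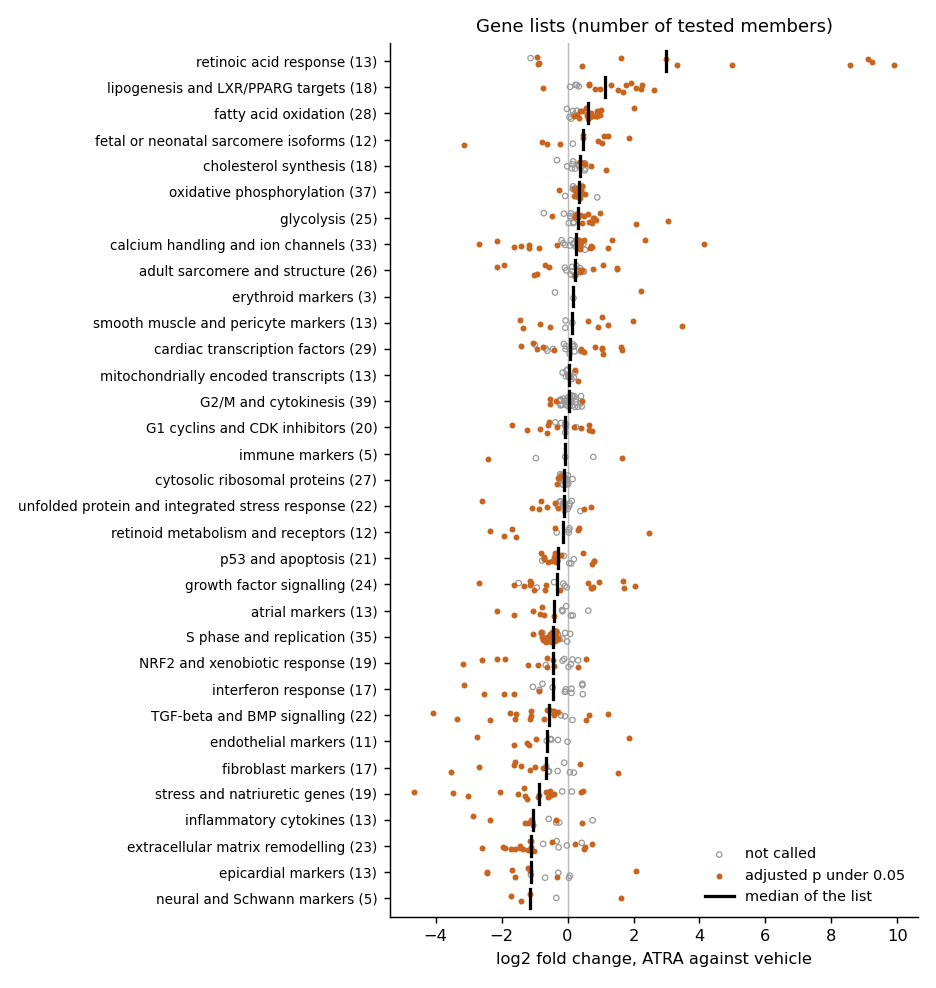
Log2 fold change after ATRA of every tested member of each gene list, filled where the adjusted p was under 0.05, with a mark at each list's median. The median is 3 for the retinoic acid response, 1.15 for lipogenesis and LXR/PPARG targets, 0.61 for fatty acid oxidation, -0.45 for S phase and -0.88 for the stress genes.

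Markers of cells other than myocytes were examined because the isolation removed fibroblasts only by pre-plating. Postn, the matricellular protein periostin, was 11.5-fold lower, from 4985 ± 2036 to 405 ± 32 normalised counts (SD, n = 3; -3.52 ± 0.29, adjusted p = 0.00011). Fbln2 was 6.38-fold lower (-2.67 ± 0.29), Loxl1, which crosslinks elastin, 3.1-fold lower (-1.63 ± 0.22) and the fibronectin gene Fn1 2-fold lower (-1 ± 0.15). The collagen gene Col1a1 was lower by a small margin (-0.73 ± 0.25, adjusted p = 0.048). Its call was lost without vehicle replicate 1 (-0.47, adjusted p = 0.068) or 2 (-0.69, adjusted p = 0.13) and without ATRA replicate 1, 2 or 3 (adjusted p = 0.13, 0.13 and 0.12), and it was -1.04 without vehicle replicate 3 (adjusted p = 0.00011). The fibroblast genes did not all follow: decorin (Dcn, 1.53 ± 0.4) and Fmod (0.39 ± 0.1) were higher, and Col3a1 (0.19 ± 0.28, adjusted p = 0.63) and Tcf21 (0.07 ± 0.37, adjusted p = 0.9) were not called, all 4 chosen after their values were seen. Of 17 tested fibroblast markers 8 were lower, 2 higher and 7 not called, the same as adjusted over the list alone (median -0.64). Camera called the list (adjusted p = 0.014), with adjusted p = 0.69 with an estimated correlation, and the call was lost with library size alone (adjusted p = 0.065). In vehicle replicate 3, 16 of the 17 markers were lower than in the mean of the other vehicle libraries, by a median of -1.12. Without that library 12 markers were lower (median -0.99), without vehicle replicate 1 the median was -0.38, and under the stricter filter it was -1. The higher count was 1 without vehicle replicate 2 or ATRA replicate 2 or 3 or under the stricter filter and 0 without ATRA replicate 1.

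**Figure D4:**
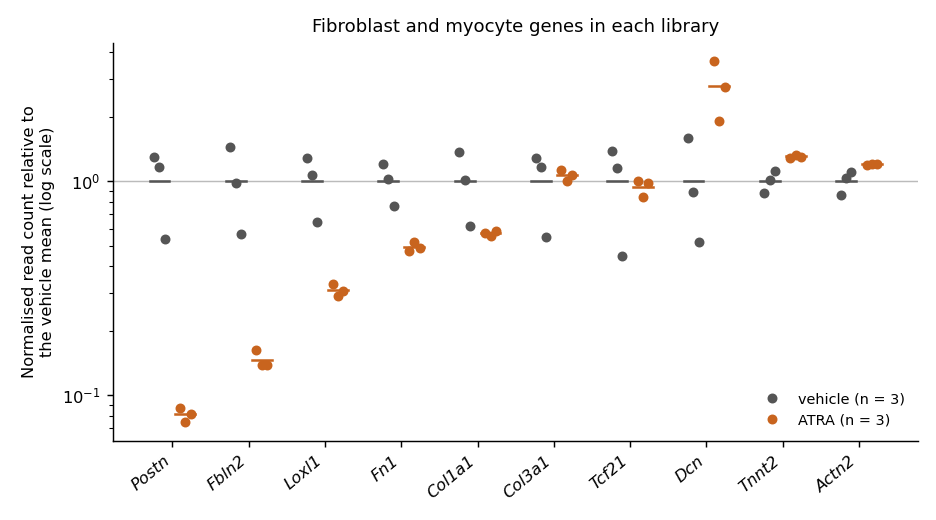
Normalised counts of 10 fibroblast and myocyte genes in each library relative to the vehicle mean, on a log axis. Postn averaged 405 normalised counts after ATRA against 4985 in vehicle; Col3a1, Tcf21, Dcn, Tnnt2 and Actn2 were added to the plot after their values were seen.

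Epicardial markers were mostly lower. Upk1b was 5.41-fold lower, from 289 ± 109 to 49.9 ± 3.93 normalised counts (SD, n = 3; -2.44 ± 0.27, adjusted p = 0.00044), and Aldh1a2 and the guidance cue Sema3d (-1.13 ± 0.18, adjusted p = 0.0024) were lower, while Krt18, a keratin also found in immature myocytes, rose 4.21-fold (2.08 ± 0.13, adjusted p = 2.7e-05). Of 13 tested, 7 were lower, 1 higher and 5 not called, the same as adjusted over the list alone (median -1.11, camera adjusted p = 0.016, and adjusted p = 0.69 with an estimated correlation). The camera call was lost with library size alone (0.061), the stricter filter (0.12, with a median of -0.32 and 4 lower) and limma-voom (0.2). In vehicle replicate 3, 12 of 13 were lower than in the mean of the other vehicle libraries (median -0.95). Without it 11 were called lower, and the median was -0.74 without ATRA replicate 3. Among 11 endothelial markers 5 were lower and 1 higher, the same as adjusted over the list alone (median -0.63, camera adjusted p = 0.1). Kdr, the main receptor for vascular endothelial growth factor, rose 3.65-fold (1.87 ± 0.09), while Flt1 was 6.61-fold lower (-2.73 ± 0.27), Eng 2.35-fold lower (-1.23 ± 0.23) and Egfl7 2.25-fold lower (-1.17 ± 0.24). Nos3 (-1.62 ± 0.51) and Tek (-0.95 ± 0.3) were the other lower ones, chosen after their values were seen. Vehicle replicate 3 was lower than the mean of the other vehicle libraries for 10 of 11 (median -0.84). Without it 9 were called lower, the median was -1.08 and camera gave adjusted p = 0.013. The median was -0.24 without vehicle replicate 1, 2 were higher with no filter, and 3 were lower without vehicle replicate 1 or 2 or ATRA replicate 1 or 2.

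Smooth muscle and pericyte markers split, with 6 of 13 higher and 4 lower, also when adjusted over the list alone (median 0.15, camera adjusted p = 0.36, or 0.022 with DESeq2). The median was 0.27 without vehicle replicate 2, 0.38 with DESeq2, 0.39 with no filter or the stricter one, 0.09 with upper-quartile factors, 0.06 with array weights and 0.04 with library size alone. Abcc9, a sulfonylurea receptor, rose 11.1-fold from 1287 ± 305 to 14064 ± 209 normalised counts (SD, n = 3; 3.48 ± 0.15, adjusted p = 4.4e-06), and Cspg4, a pericyte proteoglycan, was 2.71-fold lower (-1.44 ± 0.11). The other lower members, chosen after their values were seen, were Smtn (-0.52 ± 0.11), Pdgfrb (-1.34 ± 0.3) and Notch3 (-0.83 ± 0.21). Blood and nerve cell markers were mostly below the filter. Of 5 immune markers the macrophage receptor gene Csf1r was higher (1.65 ± 0.18) and Cd14 lower (-2.42 ± 0.31), also adjusted over the list alone (median -0.07, camera adjusted p = 0.96, median 0.11 without vehicle replicate 3 and 0.26 without ATRA replicate 2, 2 higher without vehicle replicate 3 and 2 lower with library size alone). Of 5 neural and Schwann markers Dbh, which makes noradrenaline, was higher (1.62 ± 0.1) and Tubb3 (-1.42 ± 0.2), Erbb3 (-1.15 ± 0.29) and S100b (-1.72 ± 0.49) were lower, also adjusted over the list alone (median -1.15, or -0.38 with no filter and -0.46 with DESeq2, camera adjusted p = 0.36). S100b lost its call without vehicle replicate 1 or 2 or any ATRA library (adjusted p = 0.063, 0.093, 0.06, 0.076 and 0.09) or with limma-voom (0.054) and was -2.34 without vehicle replicate 3, and Erbb3 lost its call without vehicle replicate 1 or ATRA replicate 2 or 3 (0.056, 0.054 and 0.057), which left 1 lower member without each of these 3 libraries. Of 3 erythroid markers Slc4a1 was higher, with 21 reads over the vehicle and 87 over the ATRA libraries (ratio 4.07, 95% counting interval 2.5 to 6.9), also adjusted over the list alone, and its call was lost without ATRA replicate 1 or 3 (adjusted p = 0.053 and 0.056). Its log2 fold change was 2.85 without vehicle replicate 3. The median of the erythroid markers was 0.18, or -0.13 without vehicle replicate 3, 0.41 without vehicle replicate 2, -0.14 with no filter, -0.16 with DESeq2, -0.03 with array weights and 0.05 to 0.1 with library size alone or in edgeR, and camera made no call (adjusted p = 0.6).

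Extracellular matrix genes were mostly lower. The matricellular gene Thbs1 was 5.99-fold lower, from 47601 ± 11267 to 7792 ± 350 normalised counts (SD, n = 3; -2.58 ± 0.16, adjusted p = 2.6e-05), the fibrillar collagen gene Col5a1 3.29-fold lower (-1.72 ± 0.17, adjusted p = 0.00026), the metalloproteinase inhibitor gene Timp3 2.73-fold lower (-1.45 ± 0.15, adjusted p = 0.00033) and the protease gene Adamts1 2.14-fold lower (-1.1 ± 0.12, adjusted p = 0.00038). Of 23 tested members 14 were lower, 4 higher and 5 not called, and 16 and 4 adjusted over the list alone (median -1.1). Camera called the list (adjusted p = 0.0014), with adjusted p = 0.69 with an estimated correlation. The higher members, chosen after their values were seen, were Mmp11 (0.74 ± 0.09), Lama2 (0.24 ± 0.06) and the basement membrane collagens Col4a1 (0.51 ± 0.12) and Col4a2 (0.52 ± 0.09), and 2 were higher without ATRA replicate 3. In vehicle replicate 3, 20 of the 23 members were lower than in the mean of the other vehicle libraries, by a median of -0.64. Relative to the vehicle mean the matrix genes averaged -0.82 in the ATRA libraries, and the markers of fibroblasts, epicardium and endothelium averaged -0.81, -0.82 and -0.71. On the same scale vehicle replicate 3 alone stood at -0.43 for the matrix genes and at -0.64, -0.56 and -0.65 for these markers. Its endothelial value lay within the ATRA range of -0.84 to -0.58.

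Genes of the TGF-beta and BMP signalling list were mostly lower. The activin-binding protein gene Fst was 10.1-fold lower, from 1402 ± 458 to 134 ± 23.5 normalised counts (SD, n = 3; -3.34 ± 0.24, adjusted p = 5.1e-05), and Inhba, an activin subunit, 5.15-fold lower (-2.36 ± 0.26, adjusted p = 0.00043). Id3, a BMP target, was 2.17-fold lower (-1.12 ± 0.08, adjusted p = 5.6e-05) and the ligand gene Tgfb3 1.45-fold lower (-0.53 ± 0.05, adjusted p = 0.00019). Of 22 tested, 15 were lower, 3 higher and 4 not called, and 16 and 3 adjusted over the list alone (median -0.57, camera adjusted p = 0.00018, and adjusted p = 0.36 with an estimated correlation). The higher members, Bmp7 (1.22 ± 0.14), Id2 (0.64 ± 0.11) and Bmp5 (0.55 ± 0.16), were chosen after their values were seen. The list averaged -0.88 in the ATRA libraries relative to the vehicle mean, beside -0.81 for the fibroblast markers, and was lower by a median of -0.12 in vehicle replicate 3. Other growth factor signalling genes split, with 8 of 24 higher, 10 lower and 6 not called, also when adjusted over the list alone (median -0.31, camera adjusted p = 0.48). The median was 0.61 under the stricter filter, -0.47 with no filter and -0.48 with DESeq2. Sfrp1, a secreted Wnt modulator, rose 4.15-fold (2.05 ± 0.12, adjusted p = 1.7e-05) and the ligand gene Wnt5a 3.22-fold (1.69 ± 0.13, adjusted p = 9.2e-05), while Igfbp5 was 2.21-fold lower (-1.14 ± 0.11) and the receptor gene Fgfr2 2.04-fold lower (-1.03 ± 0.13). The lower count was 6 without vehicle replicate 2 or any ATRA library or under the stricter filter. In vehicle replicate 3 the members had a median of -0.35 relative to the other vehicle libraries.

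Cytokine genes were mostly lower. Ptgs2, the inducible cyclooxygenase, was 5.15-fold lower, from 627 ± 197 to 118 ± 18.6 normalised counts (SD, n = 3; -2.36 ± 0.24, adjusted p = 3e-04), and Lif (-1.21 ± 0.12), the chemokine gene Cxcl12 (-1.1 ± 0.14) and the adhesion molecule gene Icam1 (-1.29 ± 0.19) were 2.31-fold, 2.15-fold and 2.45-fold lower. Of 13 tested inflammatory cytokines and targets 7 were lower, 1 higher and 5 not called, and 9 and 2 adjusted over the list alone (median -1.06, camera adjusted p = 0.0053, and adjusted p = 0.69 with an estimated correlation). The higher one, Vcam1 (0.45 ± 0.11), was chosen after its values were seen, and the higher count was 2 without vehicle replicate 1 or with array weights and 0 without vehicle replicate 2 or ATRA replicate 2 or 3. The median was -0.61 with no filter on low values and -0.64 with DESeq2. Vehicle replicate 3 was lower than the mean of the other vehicle libraries for 12 of the 13 (median -0.49). The cytokine genes averaged -0.86 and the interferon genes -0.69 in the ATRA libraries, beside -0.81 for the fibroblast markers. In the interferon response 5 of 17 tested genes were lower, 0 higher and 12 not called, also when adjusted over the list alone (median -0.45, camera adjusted p = 0.14). The median was 0.03 under the stricter filter, -0.29 with limma-voom, -0.3 with array weights, -0.27 without vehicle replicate 1 and -0.18 without ATRA replicate 1. Irf7, a regulator of interferon genes, was 3.81-fold lower (-1.93 ± 0.15), Oasl 5.75-fold lower (-2.52 ± 0.45), Cxcl10 8.89-fold lower (-3.15 ± 0.57, and -2.44 without ATRA replicate 2) and Gbp2 3.1-fold lower (-1.63 ± 0.4), and the remaining one was Psmb9 (-0.85 ± 0.27), chosen after its values were seen. The Gbp2 call was lost without vehicle replicate 2 or ATRA replicate 1 or 3 (adjusted p = 0.051, 0.051 and 0.052). The lower count was 3 without ATRA replicate 1 or 3 and 1 under the stricter filter, and 1 gene was higher without vehicle replicate 1, with DESeq2 or with array weights. The interferon genes had a median of -0.47 in vehicle replicate 3 relative to the other vehicle libraries.

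Most called p53 targets were lower. Of 21 tested p53 and apoptosis genes 11 were lower, 4 higher and 6 not called, and 12 and 5 adjusted over the list alone (median -0.3). Camera did not call the list (adjusted p = 0.077), but did without vehicle replicate 2 (adjusted p = 0.035). The kinase gene Plk2 (-0.71 ± 0.09, adjusted p = 0.00097) and the receptor gene Eda2r (-0.81 ± 0.12, adjusted p = 0.0019) were lower, and the survival gene Bcl2l1 (0.74 ± 0.08, adjusted p = 0.00042) and the stress-response gene Sesn1 (0.81 ± 0.09, adjusted p = 0.00047) were higher, with Ccng1 (0.48 ± 0.08) and Bcl2l11 (0.79 ± 0.15), these last chosen after their values were seen. In the unfolded protein and integrated stress response 7 of 22 tested genes were lower, 2 higher and 13 not called, also when adjusted over the list alone (median -0.12, camera adjusted p = 0.11). Ddit3, which encodes CHOP (0.7 ± 0.06), and the chaperone gene Dnajb9 (0.51 ± 0.05) were higher, and the mitochondrial folate enzyme gene Mthfd2 (-0.39 ± 0.05) and the cystine transporter gene Slc7a11 (-2.58 ± 0.38) were lower. In vehicle replicate 3, 19 of the 22 were lower than in the mean of the other vehicle libraries (median -0.19). Without that library 13 were called lower and camera gave adjusted p = 0.013, as it gave 0.041 with array weights. The median was -0.06 without vehicle replicate 1 and -0.23 with library size alone, where 11 were lower, and 4 were lower without ATRA replicate 1 or 2.

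Xenobiotic and antioxidant genes were mostly lower. Cyp1a1, the classic target of the aryl hydrocarbon receptor, was 8.92-fold lower, from 6007 ± 2746 to 630 ± 51.8 normalised counts (SD, n = 3; -3.16 ± 0.27, adjusted p = 0.00012), Nqo1 4.44-fold lower (-2.15 ± 0.26, adjusted p = 0.00064) and Gclc, which starts glutathione synthesis, 1.37-fold lower (-0.45 ± 0.06, adjusted p = 0.0013). Sod2, the mitochondrial superoxide dismutase, was 1.47-fold higher (0.56 ± 0.07, adjusted p = 0.00087), as was Sod1 (0.31 ± 0.06), chosen after its values were seen. Of 19 tested NRF2 and xenobiotic response genes 10 were lower, 2 higher and 7 not called, and 11 and 3 adjusted over the list alone (median -0.45, camera adjusted p = 0.021, and adjusted p = 0.69 with an estimated correlation). The camera call was lost without vehicle replicate 1 (adjusted p = 0.052), where 4 were higher as with array weights, and with library size alone (0.059). Cytosolic ribosomal protein genes moved little. Of 27 tested, 3 were lower, 0 higher and 24 not called, and 0 were called adjusted over the list alone, where the same limma p-values were adjusted over fewer genes. The called ones included Rps20 (-0.31 ± 0.08) and Rps2 (-0.2 ± 0.06), and the median was -0.12 (camera adjusted p = 0.021, and adjusted p = 0.69 with an estimated correlation). All 27 were lower in vehicle replicate 3 than in the mean of the other vehicle libraries (median -0.23). Without it 20 were called lower (median -0.2), 12 were lower with library size alone (median -0.23), 6 with upper-quartile factors (median -0.19) and 10 with array weights, and 0 were without vehicle replicate 2 or ATRA replicate 1, 2 or 3. The camera call was lost without vehicle replicate 1 (median -0.05, adjusted p = 0.22) or ATRA replicate 2 (adjusted p = 0.056), with DESeq2 (0.082) and with limma-voom (0.12).

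Across the 33 lists with tested members, camera called 16, of which 6 went up and 10 down, and 0 were called with an estimated correlation. The lowest adjusted p with an estimated correlation was 0.29, and 3 lists, those of the retinoic acid response, S phase and TGF-beta signalling, then had an unadjusted p under 0.05. The fry test, which asks only whether the members of a list move one way on balance, called 19, some of which camera had not called. Of the lists that camera called, fry did not call those of fibroblast markers (adjusted p = 0.21), epicardial markers (0.22) and the NRF2 and xenobiotic response (0.055). Nor did it call cholesterol synthesis (0.33) or cytosolic ribosomal proteins (0.33). By Fisher's exact test of list members among the called genes, S phase genes made up the excess with the smallest p among lower genes (28 of 35, or 80% against 18.9% of all genes tested, adjusted p = 2.8e-13) and oxidative phosphorylation genes among higher genes (30 of 37, or 81.1% against 20.3%, adjusted p = 2.3e-13).

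The authors' deposited table gave an adjusted p for 14536 genes and held 4944 with an adjusted p under 0.05, of which 2503 were higher and 2441 lower. In all, 4745 genes were called both there and in the limma test, all 4745 with the same sign, 199 only in the authors' deposited table and 405 only here. The median absolute difference in log2 fold change from the authors' deposited table was 0.004. For Cyp26a1 the authors' deposited table gave 9.92 with a standard error of 0.14, and for Corin -5.08 with 0.37.

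The first principal component held 79.4% of the variance and separated the groups, and the second held 9.4%, with vehicle replicate 3 at -28.9 and vehicle replicates 1 and 2 at 17 and 4.6. The root mean square log2 difference between libraries was 0.31 to 0.463 within vehicle, 0.25 to 0.263 within ATRA and 0.66 to 0.837 between groups. The spread over replicates was larger in vehicle than in ATRA for 76.1% of genes, with a median SD of 0.143 against 0.068 on the log2 scale. In simulated data for ATRA against vehicle over 13110 genes, of which 200 were changed, the test recovered 18%, 48%, 74% and 90% of genes changed 1.25-, 1.5-, 2- and 4-fold. With so few changed genes the adjusted threshold was stricter than in the real data, where 5150 genes were called. These shares therefore do not give the sensitivity of the real comparison. Of 128 calls in that single simulation 13 were false, a larger share than the adjusted threshold of 0.05 aims for.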

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

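The edgeR test with TMM factors and the array weights were chosen only after the result was seen; the other alternatives were planned. The number of called genes was 5146 with edgeR and TMM factors, 5159 with edgeR and DESeq2 size factors, 4986 with DESeq2, 5057 with limma-voom, 5062 with no filter, 4321 with the stricter filter, 5147 and 5151 with pseudocounts of 0.5 and 5, and 5895 with array weights. No gene called both by limma and in an alternative changed its sign. Library size alone gave 1765 higher and 3769 lower genes, with 31.9% of the calls higher in place of 51.8%, and shifted the median of all genes by -0.108. Upper-quartile factors gave 41.7% higher. At an adjusted p under 0.01 there were 2899 genes (1542 higher, 1357 lower), 2899 of them also called in the authors' deposited table. With a fold of at least 2 there were 1281 (445 and 836), 1250 of them shared in the authors' deposited comparison. Against a fold of 1.2 there were 2498 (1125 and 1373), 2485 of them shared. These last 3 settings call fewer genes by construction.

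Leaving out a library in turn gave 3360 to 6565 called genes, 1715 to 3404 higher and 1645 to 3161 lower, with the highest values without vehicle replicate 3. The sample structure, as the share of variance on the first principal component, was 62.3% with no filter, 87.4% with the stricter filter and 78.9% to 86.4% with a library left out. The replicate numbers did not pair the samples: deviations of same-numbered libraries correlated at 0, -0.1 and -0.01, and no library correlated best with its own number. With the replicate number as a block 4437 genes were called (2302 higher, 2135 lower), 4364 of them also called without it. With an estimated correlation, camera in limma called 0 lists in place of 16, with 3 at an unadjusted p under 0.05. The fry test called 19, which did not include all of the 16.

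Of 154 named genes 146 were called, and 129 of these kept their call in all settings in which they were tested (up to 20), 17 lost it in at least 1 and 0 reversed. These settings leave out the fold of at least 2, which drops smaller changes by construction. Rara was -0.05 with library size alone and Mki67 0.03 without vehicle replicate 2, neither of them called. The camera direction of lists without a call also turned, with the following medians. For immune markers it turned with upper-quartile factors (-0.06), library size alone (-0.17), no filter (-0.16), limma-voom (-0.07), edgeR with TMM factors (-0.02), and without vehicle replicate 2 (-0.04) or 3 (0.11) or ATRA replicate 2 (0.26) or 3 (-0.12), within a range of -0.36 to 0.26 over single libraries left out. For growth factor signalling it turned with library size alone (-0.42), the stricter filter (0.61), DESeq2 (-0.48) and limma-voom (-0.31), and for G2/M and cytokinesis without vehicle replicate 1 (0.05) or 2 (0.13). Over all lists and alternatives 571 results were the same, 30 lost a call, 7 gained one and 15 turned. Except where fewer genes or libraries were tested, the cause was not tested. Depth limits the genes with few vehicle reads, such as Cyp26c1 with 9 and Lrat with 10, whose fold changes rest on those reads.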

Other observations

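Of the tests in this part, the split of the libraries, the limma tests and the list medians were planned, while the gene groups in the opening paragraphs and the tests of each explanation were chosen only after the result was seen. Of 8 genes looked at, namely the aryl hydrocarbon receptor, a sensor of aromatic compounds, its partners and targets, 6 were lower and 0 higher by limma after ATRA: Ahr itself (-2.24 ± 0.32, adjusted p = 0.0014), its repressor Ahrr (-1.83 ± 0.31), and the targets Cyp1a1 (-3.16 ± 0.27), Cyp1b1 (-1.91 ± 0.28), Nqo1 (-2.15 ± 0.26) and Aldh3a1 (-3.85 ± 0.38). The partner gene Arnt (-0.02 ± 0.07, adjusted p = 0.87) and Tiparp (-0.17 ± 0.09, adjusted p = 0.15) were not called. Cyp1a1 had 9085, 5126 and 3809 normalised counts in the vehicle and 595, 690 and 606 in the ATRA libraries. Vehicle replicate 3 had the lowest vehicle value for each of the 6 lower genes, and 16 of the 17 fibroblast markers were lower in it than in the mean of the other vehicle libraries. Immediate early genes were lower in 11 of 11 cases, from Jund (-0.86 ± 0.18) to Fosb (-4.84 ± 0.23), with Egr1 at -3.03 ± 0.23 and Jun at -1.5 ± 0.12.

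Of the KATP channel genes looked at, the regulatory subunits Abcc9 (3.48 ± 0.15) and Abcc8 (0.76 ± 0.11) were higher, while the pore genes Kcnj11 (0.17 ± 0.14, adjusted p = 0.38) and Kcnj8 (-0.07 ± 0.41, adjusted p = 0.9) were not called. Of 6 genes for serine synthesis and amino acid uptake 4 were lower, namely Slc7a11 (-2.58 ± 0.38), Psat1 (-1.09 ± 0.23), Slc7a5 (-0.88 ± 0.16) and Phgdh (-0.79 ± 0.21), and vehicle replicate 3 had the lowest vehicle value for each of these 4.

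The real split of the 6 libraries called 5150 genes and the highest of the others 0 by limma, with 48 to 313 genes at an unadjusted p under 0.05, so 1 of the 10 splits called that many, and 10 splits are too few for a share under 0.05.

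Of 17 fibroblast markers 8 were lower after ATRA, 2 higher and 7 not called, with camera adjusted p = 0.014, or adjusted p = 0.69 with an estimated correlation. Fewer fibroblasts as the whole cause would lower all markers by a common amount, if only fibroblasts made them. The SD of their log2 fold changes, 1.18, was 4.15 times their median standard error of 0.28, with Dcn higher and Postn lower. Markers that other cells also make would fall less, so this spread cannot decide for the lower markers. Fewer fibroblasts alone would not raise the 2 higher ones if only fibroblasts made them. The values are relative, so a larger share of other cells that make them could raise them, and they cannot decide either. The higher count was also 0, 1 and 1 without ATRA replicate 1, 2 and 3. A single misplaced vehicle library is argued against, since at least 6 markers were called lower with any library left out. Leaving out 1 library does not cover a spread of fibroblast content over all vehicle libraries. The marker means of vehicle replicates 1 to 3 were 0.43, 0.21 and -0.64 relative to the vehicle mean, beside -0.89 to -0.74 after ATRA. For Col1a1 alone, fewer fibroblasts cannot be told apart from lower expression per cell, because its ATRA mean lay 0.11 below the lowest vehicle library on the log2 scale, within the vehicle SD of 0.58. A change of matrix gene expression within fibroblasts or myocytes stays open and was not tested.

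Of 35 S phase genes 28 were lower, while G2/M genes had a median of 0.03. Fewer cycling cells would lower both lists. The G2/M median lay 0.47 above that of S phase, beyond the SD over members of 0.24 in each list. Without vehicle replicate 3 the medians were -0.1 for G2/M and -0.47 for S phase. In that library all 39 G2/M genes were lower than in the mean of the other vehicle libraries. The G2/M members moved together (estimated correlation 0.761), and their mean ran from -0.25 to 0.21 over the vehicle libraries, relative to the vehicle mean. The SD over members does not cover that spread, so fewer cycling cells stay open. With the trend over gene length and expression level removed, the difference was 0.49 (SDs 0.2 and 0.23), which argues against such a trend. A hypothesis that also stays open is that ATRA may lower replication genes, or shift the share of cells in each phase, without lowering the number of cells that express mitotic genes, which was not tested.

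Of 37 oxidative phosphorylation genes 30, and of 28 fatty acid oxidation genes 22, were higher. Short transcripts favoured in the ATRA libraries would raise ribosomal protein genes too, but the oxidative phosphorylation median lay 0.46 above theirs (SDs 0.17 and 0.1). The members of each list moved together (estimated correlations 0.792 and 0.826). Relative to the vehicle mean, vehicle replicates 1 to 3 had -0.13, 0 and 0.12 for oxidative phosphorylation and 0.14, 0.02 and -0.16 for ribosomal protein genes. The SD over members does not cover that spread, so the 0.46 alone cannot decide. The ribosomal mean was -0.14 to -0.1 in the ATRA libraries, so no rise was seen. A larger share of myocyte RNA would raise adult sarcomere genes as much, and the fatty acid oxidation median lay 0.37 above the sarcomere median (95% bootstrap interval 0.09 to 0.62, 10000 resamples). That share cannot be told apart from higher expression, because the sarcomere genes went both ways with an SD of 0.86, a reading added after the interval was seen. For oxidative phosphorylation the difference of the medians was 0.09 (-0.05 to 0.29). The difference of the list means per library, relative to its vehicle mean and also added afterwards, did not overlap between groups (-0.08 to 0.12 in vehicle, 0.22 to 0.27 in ATRA). This leaves that share open as well.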
